A study of Drosophila melanogaster with 8 samples.

How the data were processed

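Polyadenylated RNA from sorted clock neurons of adult brains was sequenced in 8 libraries, 2 at each of circadian times 0, 6, 12 and 18 h, all from flies with mor RNA interference driven by Clk-GAL4. Per the labels, cells positive for nuclear green fluorescent protein and negative for DAPI were sorted. Per the labels, cDNA was made with a NEBNext low-input kit, fragmented with Nextera XT and read as paired ends. The labels give no library or sequencing batches. Groups follow the circadian time in the labels.

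The deposited files are gene tables in the layout of Salmon. Per the file headers they hold, for 17868 genes named by symbol, a length and an effective length in bases, a TPM value and an estimated (expected) count. The deposited estimated counts were not normalized, and between 12.8% and 15.0% of values per library were not whole numbers. The deposited TPM values sum to the same total in each library. DRAGEN, Salmon and the build dm6 are named in the submitters' processing notes, and their roles, versions and annotation are not given in the sources used here. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Reads shared by near-identical copies, such as those of Hsp70 or ribosomal RNA, were assigned by a method that is not given in the sources used here.

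Counts were rounded, and genes were kept by edgeR's filterByExpr with times as groups and a minimum count of 10, which left 9999 of the 13497 genes with a count. TMM factors were used, and all values in CPM are TMM-normalized. Total counts were 29346348 and 24680842 at CT0 (replicates 1 and 2), 28031483 and 21928087 at CT6, 28447624 and 15006258 at CT12, and 27232908 and 18863901 at CT18. The floor given for each library is 3 counts of its total.

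The test for single genes was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on all 8 libraries with time as a factor, 4 residual degrees of freedom per gene and Benjamini-Hochberg adjustment at 0.05. The prior degrees of freedom were 5.4 and the median biological coefficient of variation was 0.31. The tests were any change over the 4 times, a 24-hour harmonic (2 degrees of freedom, the differences CT0 minus CT12 and CT6 minus CT18), a 12-hour component, CT12 minus CT0 and CT18 minus CT6. Amplitudes run from mean to peak in log2 units, and amplitudes and changes are given with their standard error. The step was tested on simulated data with 200 changed genes among 9559, and it called 1 of 9359 unchanged genes.

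There were 28 gene lists: clock genes and their modifiers, the Brahma complex, cycling outputs of heads, peptides and receptors of clock neurons, markers of cell types, transmitters, ion channels, stress, immune and metabolic genes, male dosage compensation RNAs and transgene markers. Of these, 25 had at least 3 tested members and were tested with limma 3.58.1 (camera with a preset correlation of 0.01, beside an estimated correlation and fry). Values adjusted over the list alone apply the Benjamini-Hochberg adjustment within 1 list. They are not adjusted over the 28 lists or over the tests, so some such passes can arise by chance. Mitochondrially encoded genes were taken from the RefSeq table, because the symbol pattern matched none. Single values per library (mor, the clock index and list means, as log2 CPM with a prior count of 1) were compared between times by an exact permutation test of the sum of squares between times over all splits of the libraries into pairs. Tests were two-sided. Spread between duplicates was set against 10000 random lists of the same size matched on expression. Correlations over libraries have exact permutation p-values.

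Named genes followed a rule: every core clock and Brahma complex gene, the genes passing a test or, where none passed, the 5 with the smallest p, and in every other list the 2 with the smallest p where none passed. Genes that pass over their list alone, and other neuropeptide genes, were named after their values were seen. Coordinates are from the Ensembl release 115 annotation of BDGP 6.54, which need not be the one the authors used.

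The alternatives were RLE normalization, no filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, log2 TPM with pseudocounts of 1 and 0.1, a prior count of 5, a replicate block, an effective length offset, no mitochondrial genes, the libraries of a contrast alone, and leaving out each library in turn. A robust prior, and the removal of each library's lowess trend (span 0.3) of expression against effective length, fitted on genes with a mean log2 CPM of at least 4, were added after the data were seen. Scripts ran in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Control libraries and chromatin accessibility were left out because only the 8 knockdown libraries were analysed here.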

Results

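RNA was sequenced from clock neurons sorted out of adult Drosophila brains in which the gene mor was targeted by RNA interference. The neurons carried a nuclear green fluorescent protein under Clk-GAL4, a driver active in the circadian pacemaker network. Flies were entrained to cycles of light and dark and collected on the second day of constant darkness, at circadian times (CT) 0, 6, 12 and 18 h. Each of the 4 times had 2 libraries, 8 in all, and total estimated counts per library ran from 15006258 (CT12 replicate 2) to 29346348 (CT0 replicate 1). A count of 3 corresponds to between 0.102 and 0.2 CPM (counts scaled to library size), and this floor covers counting error only. Between 10208 and 10806 genes had a count in a library. The labels do not say what the replicates share, so p-values measure only the spread between these libraries. All libraries come from the knockdown genotype, and the comparison across times asks which transcripts change over the circadian day in these neurons. Control libraries and chromatin accessibility, also part of the study's design, were not analysed here.

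The targeted gene, mor (FBgn0002783, 3R 15968134 to 15972913), encodes a core subunit of the Brahma chromatin remodelling complex. Its transcript was detected in all 8 libraries, at low levels, with 2144 estimated counts in all. TMM-normalized values were 11.5 and 13.0 CPM at CT0 (mean 12.3 ± 1.1 SD, n = 2). At CT6 they were 21.8 and 7.9 CPM (14.8 ± 9.8), at CT12 11.4 and 13.2 CPM (12.3 ± 1.3), and at CT18 4.1 and 4.4 CPM (4.27 ± 0.193). The CT18 libraries were thus the lowest 2 of the 8, but the difference between times did not pass an exact permutation test over all splits of the libraries into pairs (two-sided, p = 0.14; smallest possible 0.0095). Without CT6 replicate 1, or without CT6 replicate 2, the exact p was 0.029. These values do not measure the knockdown, which needs a control genotype. They also largely followed how counts tracked gene length in each library, described below. The Spearman correlation of a library's deviation with effective length was −0.533 and −0.563 at CT18 and 0.684 in CT6 replicate 1. The low values of mor at CT18 are thus not separated from that trend. Of the 12 Brahma complex genes, including brm, Snr1, osa, Bap60, Bap55, Bap111, polybromo, Bap170, e(y)3, tth and CG7154, 0 had a 24-hour harmonic in edgeR when adjusted over the list alone (smallest adjusted p = 0.3) or over all genes.

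Of the 8 core clock genes, 4 changed with time of day when adjusted over the list alone, and 0 did over all genes in edgeR with its filter on low counts, while DESeq2, and edgeR without that filter, each called 3 (vri, Clk and tim) over all genes. Mean transcript levels of tim and vri, direct targets of the CLOCK and CYCLE activators that encode repressors of the clock, were highest at CT12. Pdp1, an activator in the interlocked loop, had a later fitted peak, although its means at CT12 and CT18 were close (787.1 and 769 CPM). Clk, which encodes the activator itself, had its highest mean at CT0. In replicate 1 alone, tim, vri and Clk were each highest at CT6 (379.2, 226.3 and 111.8 CPM, against 319.1 and 154.5 CPM for tim and vri at CT12 and 86.7 CPM for Clk at CT0). Transcripts of cyc, which encodes the partner of CLOCK, stayed within 45.1 to 67.2 CPM. The mean of vri went from 42.1 ± 4.36 CPM at CT0 to 261.5 ± 151.4 at CT12 (SD, n = 2), that of tim from 108.0 ± 27.4 to 481.7 ± 229.9, and that of Clk from 191.8 ± 148.7 down to 34.3 ± 15.5. The core clock genes had a median SD between libraries of the same time of 0.66 log2 units, against a median of 0.29 in random lists of like expression (percentile 100). Without the filter, edgeR did not use each gene's own spread, so its 3 calls take no account of this.

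In edgeR's test of a 24-hour harmonic, 4 of the 8 core clock genes passed when adjusted over the list alone, and 0 passed when adjusted over all 9999 genes tested (adjusted p of 0.87 or more, against 3 called by DESeq2 and by edgeR without a filter). The fitted amplitude of vri (2L 5288944 to 5311223) was 1.33 ± 0.26 log2 units (SE), a 6.28-fold range with a peak at 11.6 h, and it ranked 13 of all genes. For Clk (3L 7763233 to 7775603) it was 1.42 ± 0.29 with a peak at 1.9 h, rank 24. For tim (2L 3493986 to 3508119) it was 1.08 ± 0.23 with a peak at 12.2 h, rank 33. These 3 genes had an adjusted p of 0.01 over the list alone. With a library left out, the amplitude ran from 0.95 to 1.57 for vri, 0.96 to 1.7 for Clk and 0.78 to 1.29 for tim. The fitted peak then ran from 10.8 to 12.9 h for vri, 1.3 to 3 h for Clk, 11.4 to 13.4 h for tim and 14.7 to 16.3 h for Pdp1. For Pdp1 (3L 7811458 to 7867369) the amplitude was 0.54 ± 0.15 with a peak at 15.6 h, rank 126, with an adjusted p of 0.03 over the list alone. The remaining core genes did not pass: per (amplitude 0.63 ± 0.28, adjusted p = 0.21), cwo (0.27 ± 0.19, adjusted p = 0.51), cry (0.38 ± 0.29, adjusted p = 0.52) and cyc (0.04 ± 0.14, adjusted p = 0.97). Clk alone kept its call whichever library was left out. Without CT0 replicate 1, tim, vri and Pdp1 each had adjusted p = 0.066. Without CT12 replicate 2, tim had adjusted p = 0.054 and Pdp1 adjusted p = 0.07. Pdp1 also lost its call without CT0 replicate 2 (adjusted p = 0.068) and without CT18 replicate 1 (adjusted p = 0.09).

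**Figure D1:**
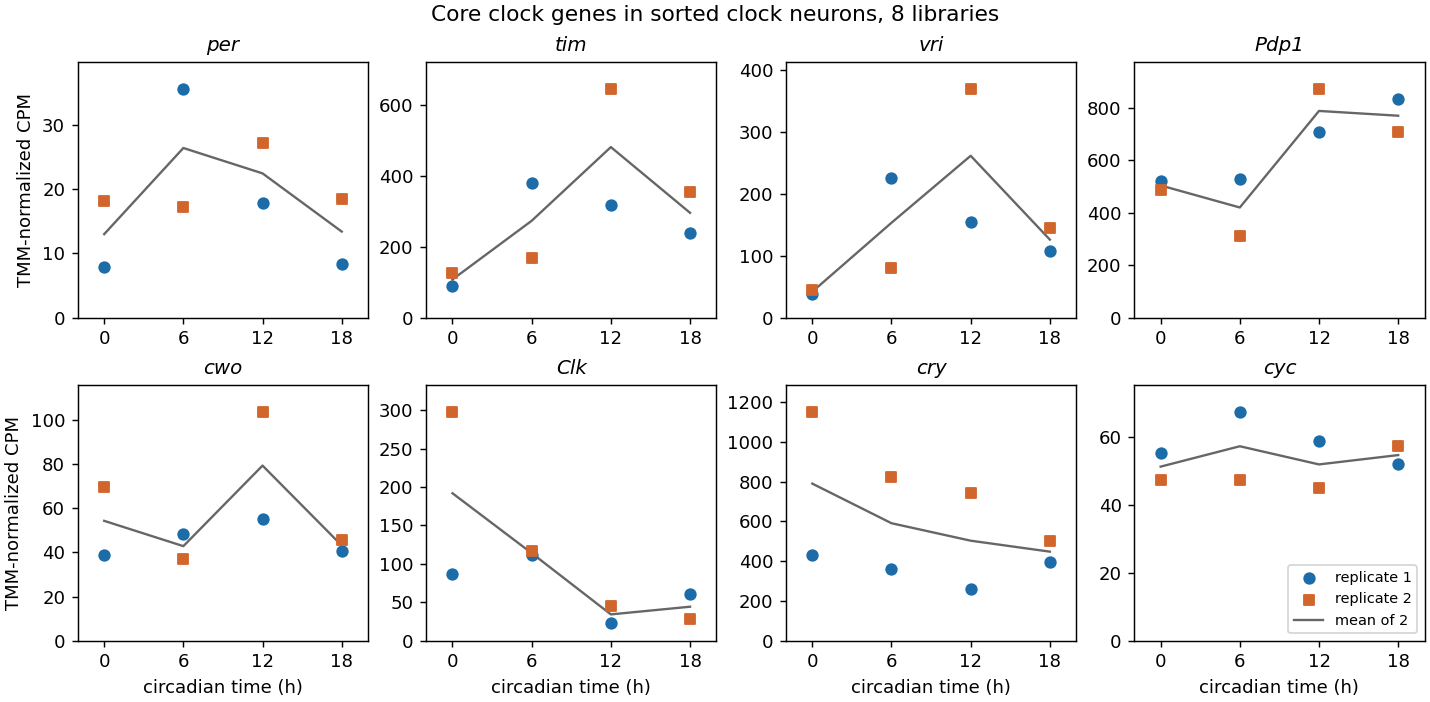
TMM-normalized CPM (vertical axes) of the 8 core clock genes against circadian time in hours (horizontal axes), 1 point per library, with the line through the mean of the 2 libraries. In tim and vri both CT12 libraries lie above both CT0 libraries, in Clk both lie below them, and cyc stays between 45.1 and 67.2.

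A clock index, the mean log2 CPM of per, tim, vri, Pdp1 and cwo minus that of Clk and cry, was lowest at CT0 (−2.32 ± 0.75 SD, n = 2). It was −1.21 ± 1.13 at CT6, 0.50 ± 0.29 at CT12 and −0.32 ± 0.56 at CT18. The difference between times did not pass the exact permutation test over all splits into pairs (two-sided, p = 0.095). Without CT6 replicate 1 the exact p was 0.048.

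Across the transcriptome, 0 of 9999 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in any of the 5 tests. For the 24-hour harmonic the smallest adjusted p was 0.74, and 517 genes had an unadjusted p under 0.05, where 500 is the nominal expectation. Other assignments of libraries to times gave a median of 313, and 27 of 101, the real one included, gave 517 or more. DESeq2 called 33 genes for the same harmonic, 3 of them core clock genes (vri, Clk and tim), and limma-voom called 0. The 33 also held ribosomal RNA entries, among them 28SrRNA:CR45844 (DESeq2 adjusted p = 0.02) and pre-rRNA:CR45847 (0.012). Without the filter on low counts edgeR called 250, with tim (adjusted p = 4.3e-08), vri (3.1e-13) and Clk (4.3e-15) among them. That fit had infinite prior degrees of freedom, so it used a spread common to genes of like expression and no gene's own. The core clock genes spread more than random lists of like expression (median SD 0.66 against 0.29 log2 units). For any change over the 4 times the unadjusted count was 330, below the nominal 500, with 28 called by DESeq2 and 0 by limma-voom. For a 12-hour component it was 238, also below 500, with 5 by DESeq2 and 0 by limma-voom. On simulated counts the harmonic test recovered 0% of 50 genes with an amplitude of 0.5 log2 units, 18% at 1, 60% at 1.5 and 84% at 2. Rhythms of up to about 1 log2 unit would therefore mostly not pass the adjustment with these 8 libraries. The simulation held 200 changed genes, which eases the adjustment, so with fewer changed genes larger rhythms could also fail. In the real data vri and Clk, with fitted amplitudes of 1.33 and 1.42, had an edgeR adjusted p of 0.87. The 5 genes with the smallest p were E(spl)m6-BFM (amplitude 1.43 ± 0.18, peak 16.9 h), glob1 (0.72 ± 0.11, peak 22.0 h), Trh (0.84 ± 0.13, peak 5.7 h), CG31324 (0.84 ± 0.14, peak 13.5 h) and Irc (1.39 ± 0.24, peak 17.3 h). None of them passed in edgeR, with adjusted p of 0.74 for E(spl)m6-BFM and 0.87 for the rest, while DESeq2 called all 5.

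Lists were compared between the start of the subjective day (CT0) and the start of the subjective night (CT12). In camera, though not by fry, the evening clock genes had the smallest adjusted p of the 25 lists. These genes, per, tim, vri, Pdp1 and cwo, were all higher at CT12, a call made with a preset correlation and lost with an estimated one (adjusted p = 0.47) and by fry (0.58). Of the 5, tim and vri passed as single genes over the core clock list alone, each rising by more than 2 log2 units, and per, Pdp1 and cwo did not. Clk and Ugt35B1, a glycosyltransferase whose transcript cycles in fly heads, fell by the same kind of test. Of the neuropeptide genes of clock neurons, 9 of 15 were lower at CT12 (median −0.26 log2 units), a list call lost with an estimated correlation (adjusted p = 0.49) and by fry (0.12).

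The evening clock genes had an adjusted p of 3e-12 in limma's camera with a preset correlation, and 0.47 with an estimated correlation. This call stayed under 0.05 whichever library was left out, at most 0.0013 (without CT12 replicate 2). The other calls were the core clock list (Up, adjusted p = 0.0032; 0.55 with an estimated correlation), hemocyte markers (Up, 0.026; 0.55), activity-regulated genes (Up, 0.027; 0.55) and clock neuron peptides (Down, 0.027; 0.49), so 5 of the 25 lists passed and 0 did with an estimated correlation or by fry. The core clock list lost its call without CT0 replicate 1 (0.95) and without CT12 replicate 2 (0.36). The activity list lost it without CT0 replicate 1 (0.99, direction turned) and without CT12 replicate 2 (0.23). The hemocyte list lost it without CT12 replicate 1 (0.24, direction turned), without CT0 replicate 2 (0.39) and without CT6 replicate 2 (0.13). Hml and NimC1, hemocyte genes, reached 25.0 and 29.7 CPM in CT12 replicate 1 alone. The peptide list lost it without CT0 replicate 1 (0.17), CT6 replicate 1 (0.058), CT12 replicate 1 (0.13) or CT6 replicate 2 (0.16). Without CT0 replicate 2, 10 lists passed. Glia, photoreceptor and mitochondrially encoded genes tested Up without passing (adjusted p = 0.67, 0.1 and 0.63), against medians of −0.09, −0.07 and −0.03 log2 units, and their results hung on single libraries. Without CT0 replicate 1, glia (Up, 0.00045) and mitochondrially encoded genes (Up, 4.5e-06) passed, and without CT0 replicate 2 both passed in the opposite direction (Down, 0.017 and 0.0093). Photoreceptor genes passed as Up without CT0 replicate 2 (2.4e-08) or CT12 replicate 2 (0.02), and tested Down without CT0 replicate 1 (0.28). Ribosomal proteins (Down) passed under 4 of 8 left-out libraries, oxidative phosphorylation (Down) under 3 and heat-shock genes (Up) under 1.

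For single genes in this contrast, 0 of 9999 passed in edgeR (smallest adjusted p = 1). There were 211 genes under an unadjusted p of 0.05, where 500 is the nominal expectation. Of the 211, 129 were higher and 82 lower at CT12. DESeq2 called 12 and limma-voom 0. When adjusted over the list alone, 3 core clock genes passed. These were vri (2.64 ± 0.53 log2 units, adjusted p = 0.0045), tim (2.16 ± 0.47, adjusted p = 0.0045) and Clk (−2.49 ± 0.59, adjusted p = 0.0055), the last of which had adjusted p = 0.054 without CT0 replicate 2. Among the head cycling outputs, Ugt35B1 changed by −3.27 ± 0.73 log2 units (adjusted p = 0.0097 over the list alone) and kept its call under every left-out library. The 5 smallest p belonged to CG31324 (1.55 ± 0.27), glob1 (−1.24 ± 0.23), CG17777 (−1.72 ± 0.34), vri and Eip63F-1 (−1.29 ± 0.26), with adjusted p of 1 in edgeR.

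Between the middle of the subjective day (CT6) and the middle of the subjective night (CT18), the heat-shock and activity-regulated lists were lower at CT18 with a preset correlation, but not with an estimated one (adjusted p = 0.67 each) or by fry (0.42 and 0.40). All 15 heat-shock genes tested were lower, among them the Hsp70 copies, Hsp68 and stv, whose products refold damaged proteins, and CT6 replicate 1 held the highest heat-shock mean of the 8 libraries (11.11 log2 CPM, against 9.75 to 10.38). Trh, the neuronal tryptophan hydroxylase that makes serotonin, fell when adjusted over the list alone, whichever library was left out. SerT, the serotonin transporter, the endoplasmic reticulum chaperones Hsc70-3 and Gp93, and sr, a transcription factor induced by neuronal activity, passed over their lists alone with all 8 libraries, but not without CT6 replicate 1 or without CT18 replicate 1. None of these genes passed over all genes (edgeR adjusted p = 0.51), and adjustment within a list takes no account of the number of lists. The lists of oxidative phosphorylation (58 of 67 members), ribosomal (72 of 83) and proteasome genes (27 of 35) leaned higher at CT18, but 0 of their members passed over the list alone, and none of the 3 lists passed as higher with the length trend removed. These are short genes, with median effective lengths of 431, 368 and 1112 bases against 1607 for all genes, and the libraries differed in how counts followed gene length.

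In this contrast, 8 of 25 lists passed camera with a preset correlation, and 0 did with an estimated correlation or by fry. Lists lower at CT18 were heat-shock genes (adjusted p = 4.2e-07; 0.67 with an estimated correlation; median −0.86 log2 units), activity-regulated genes (0.0049; 0.67; 7 of 7 lower), the unfolded protein response (0.0097; 0.67; 10 of 12 lower) and hemocyte markers (0.031; 0.75; 9 of 10 lower). Lists higher at CT18 were oxidative phosphorylation (5.6e-10; 0.67; 58 of 67 higher), ribosomal proteins (0.001; 0.83; 72 of 83), glia (0.023; 0.75; 10 of 12) and the proteasome (0.023; 0.83; 27 of 35). Without CT6 replicate 1 the heat-shock list kept an adjusted p of 0.0034, while the unfolded protein response had 0.055, the proteasome 0.75 and ribosomal proteins turned Down at 0.15. The unfolded protein response also lost its call without CT18 replicate 1 (0.13), hemocyte markers lost theirs without CT18 replicate 1 (0.14) or CT6 replicate 2 (0.23), glia without CT6 replicate 2 (0.23) and the proteasome without CT18 replicate 2 (0.37). Lists that did not pass with all 8 libraries but did with 1 left out were mitochondrially encoded genes (Up, 0.028 without CT6 replicate 1 and 0.0037 without CT18 replicate 2), photoreceptors (Up, 0.00038 without CT18 replicate 1), transmitters (Down, 0.0018 without CT6 replicate 2), and the Brahma complex and Kenyon cell genes (Down, 0.024 and 0.04 without CT18 replicate 2), besides the evening clock genes and ion channels below.

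Gene length separated the libraries. The Spearman correlation, across 5766 genes, between effective length and a library's deviation from the others was 0.684 in CT6 replicate 1 and −0.223 in CT6 replicate 2. It was −0.533 and −0.563 in the CT18 libraries, −0.342 and 0.412 at CT0, and −0.114 and 0.468 at CT12. Genes are not independent replicates, so these values describe the libraries. With each library's trend against length removed, the heat-shock list (Down, camera adjusted p = 3.2e-10), activity-regulated genes (Down, 0.047), the unfolded protein response (Down, 0.019) and glia (Up, 0.0045) still passed. Oxidative phosphorylation (0.54), the proteasome (0.85) and hemocyte markers (0.061) did not, and ribosomal proteins changed direction (Down, 0.00014). The evening clock genes (Up, 0.0062) and ion channels (Up, 0.019) passed after the removal and without CT6 replicate 1 (0.014 and 0.0062), while ion channels tested Down without CT6 replicate 2 (0.014). The evening clock genes tested Down without CT6 replicate 2 or without CT18 replicate 2. Between CT0 and CT12 the evening clock genes (7.4e-15) and the core clock list (0.00023) still passed, and hemocyte markers (0.054), activity-regulated genes (0.054) and peptides (0.1) did not. All calls with the length trend removed used the preset correlation. With an estimated correlation or by fry no list passed before the removal, and these were not run after it.

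For single genes between CT6 and CT18, 0 of 9999 passed in edgeR (smallest adjusted p = 0.29). There were 965 genes under an unadjusted p of 0.05, where 500 is the nominal expectation. Of the 965, 276 were higher and 689 lower at CT18. DESeq2 called 47 and limma-voom 0. CT6 replicate 1 and the CT18 libraries lay at opposite ends of the length trend, so these counts are not separated from it. When adjusted over the list alone, 6 heat-shock genes passed, among them Hsp70Ab (−1.71 ± 0.47 log2 units, adjusted p = 0.019), Hsp68 (−1.45, adjusted p = 0.03) and stv (−1.28, adjusted p = 0.037). The Hsp70 copies are near-identical, so their reads cannot be assigned to single copies with certainty. Hsp70Ab, Hsp70Ba, Hsp70Bbb and Hsp70Bc were among the 6, so these are not 6 separate signals. Without CT6 replicate 1 the heat-shock genes had adjusted p of 0.24 to 0.35, and without CT18 replicate 1 adjusted p of 0.091 to 0.13, so none of the 6 passed. Hsp68 and stv also had adjusted p = 0.057 without CT18 replicate 2. Trh changed by −1.68 ± 0.27 (adjusted p = 0.0016 over the list alone) and kept its call under every left-out library. SerT changed by −1.30 ± 0.34 (adjusted p = 0.022), but had adjusted p = 0.17 without CT6 replicate 1, 0.065 without CT18 replicate 1 and 0.11 without CT18 replicate 2. For sr the change was −1.78 ± 0.40 (adjusted p = 0.0095), with adjusted p = 0.085 without CT6 replicate 1 and 0.066 without CT18 replicate 1. Gp93 (−1.56 ± 0.38, adjusted p = 0.031) and Hsc70-3 (−1.49 ± 0.42, adjusted p = 0.032) had adjusted p of 0.15 and 0.22 without CT6 replicate 1 and of 0.24 each without CT18 replicate 1. With the length trend removed, stv (0.061), Gp93 (0.057) and Hsc70-3 (0.089) no longer passed, and the other genes named here did.

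The 5 smallest p between CT6 and CT18 belonged to E(spl)m6-BFM, a Notch target (2.74 ± 0.37 log2 units), Trh, Irc (2.73 ± 0.48), Edc3 (−1.47 ± 0.26) and Rat1 (−1.51 ± 0.29), with edgeR adjusted p of 0.29 for E(spl)m6-BFM and 0.51 for the others. Among Kenyon cell markers, prt and Pka-C1 had an adjusted p of 0.037 over the list alone. Each lost that call under 4 of 8 left-out libraries (p up to 0.22 and 0.16), and both had 0.13 with the length trend removed. The eye colour gene w, which transgenes also carry and which was the only tested member of its list, fell by 1.86 log2 units over that list (adjusted p = 0.0026) but did not pass over all genes in edgeR (adjusted p = 0.51). Between CT0 and CT12 w had an adjusted p of 0.047 over the list, a call kept under 2 of 8 left-out libraries (up to 0.43). The other member, v, was near the floor, at up to 1.0 CPM.

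**Figure D2:**
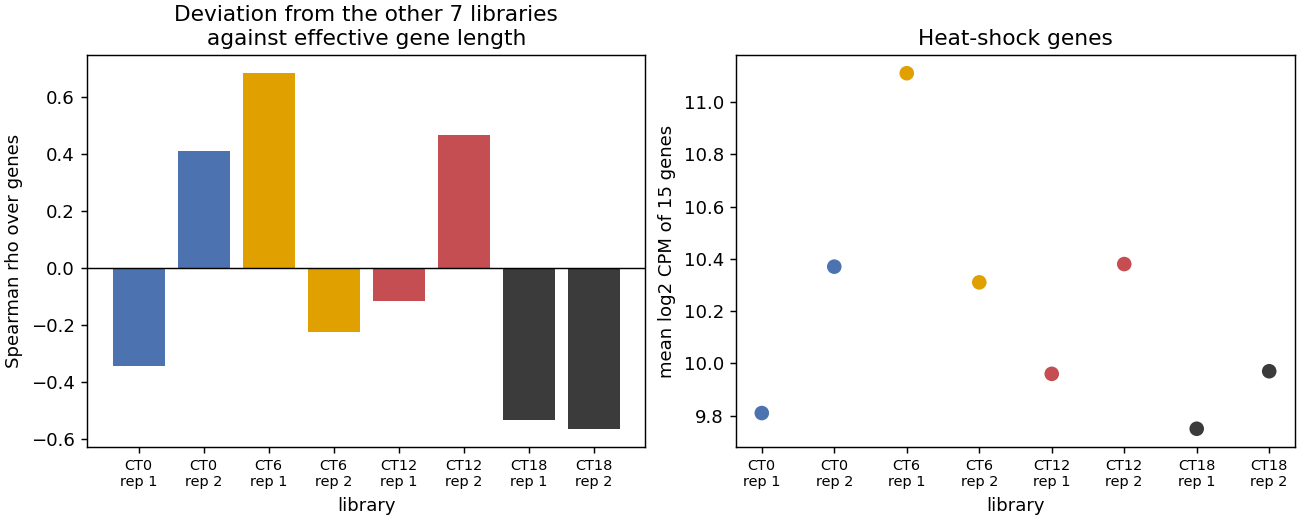
Per library, the Spearman correlation across genes between effective gene length and the deviation from the other libraries (no unit), and the mean log2 CPM of the 15 heat-shock genes, with a colour for each circadian time. CT6 replicate 1 is the highest library in both, at 0.684 and 11.11.

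As means over lists, neuronal markers stood above those of other cell types in every library. The mean log2 CPM of 12 pan-neuronal genes stayed between 8.50 and 8.81, and markers of glia (0.19 to 2.56), fat body (0.88 to 3.04), muscle (−2.34 to −0.59), photoreceptors (−0.83 to 2.87) and hemocytes (−1.07 to 3.89) stayed below them. Single markers overlapped: 6 of them (Arr2, ninaE, norpA, Gs2, nrv2 and FASN1) exceeded the neuronal gene elav in at least 1 library, among them Arr2 at 252.7 against 119.3 CPM in CT0 replicate 2, ninaE at 177.1 against 122.6 CPM in CT18 replicate 2 and Gs2 at 129.8 against 112.8 CPM in CT12 replicate 1. Kenyon cell genes, which other neurons share, stayed between 5.08 and 5.83. Neuropeptide genes, which mark subsets of clock neurons, differed widely between libraries of the same time. Pdf, the peptide of the ventral lateral neurons (3R 26455462 to 26456141), was at 21182 and 26519 CPM at CT0 and at 8822 and 18007 CPM at CT12. It was at 89.3 CPM in CT6 replicate 1 against 37187 in CT6 replicate 2, and at 1647 and 14088 CPM at CT18. NPF ranged from 10.5 to 2748 CPM and Trissin from 9.0 to 1674 CPM, while AstC, shared by dorsal neurons, varied 1.72-fold. Of the 12 lists of cell type and RNA quality genes, 0 passed the exact permutation test of a difference between times over all splits into pairs (adjusted p from 0.72 to 0.89, two-sided). With pairs of libraries this test cannot go below 0.0095 before adjustment, so over 12 lists no list could pass on its own. The 0 was therefore nearly fixed in advance and does not show that composition was equal between times. Before adjustment the smallest exact permutation p was 0.11 (muscle markers).

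**Figure D3:**
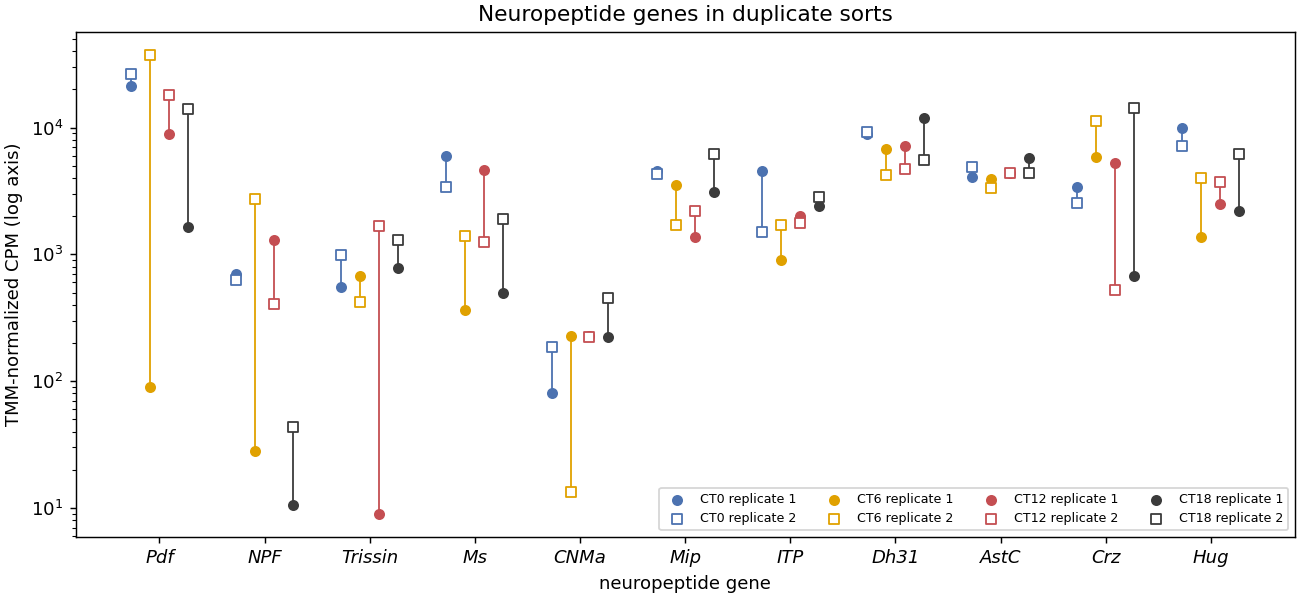
TMM-normalized CPM (log axis) of neuropeptide genes, 1 point per library, with circles for replicate 1, squares for replicate 2 and a colour for each circadian time. Pdf runs from 89.3 in CT6 replicate 1 to 37187 in CT6 replicate 2, while AstC varies 1.72-fold.

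In the lists not described so far, few genes passed the harmonic test when adjusted over the list alone, with no adjustment for the number of lists. In edgeR these were Ugt35B1 (adjusted p = 0.016), Trh (adjusted p = 0.0056; 0.077 without CT18 replicate 1) and sr (adjusted p = 0.026; 0.17 without CT6 replicate 1, 0.15 without CT18 replicate 1, 0.099 without CT18 replicate 2). The gene w passed as well, as the only tested member of its list, so that no adjustment applied (adjusted p = 0.0036, and 0.0019 to 0.035 with a library left out). Over all genes w had an adjusted p of 0.87 in edgeR and of 0.038 in DESeq2. The members with the smallest p in the lists where 0 passed were sgg and kay (clock modifiers), Mip and NPF (peptides), Dh44-R1 and CNMaR (receptors), Syt1 and Syx1A (pan-neuronal), Eaat1 and Mdr65 (glia), ninaE and Rh4 (photoreceptor), Yp1 and Yp2 (fat body), srp and Nplp2 (hemocyte), Mlc1 and Mlc2 (muscle), and Pka-C1 and prt (Kenyon cell). They were also KCNQ and Shaw (ion channels), Hsp70Bc and Hsp70Ba (heat shock), Gp93 and Hsc70-3 (unfolded protein response), Drs and AttD (antimicrobial peptides), PyK and Pfk (glycolysis), RpS12 and RpS13 (ribosomal), SdhB and SdhD (oxidative phosphorylation), Rpn2 and Prosbeta2 (proteasome), and COX1 and ND4 (mitochondrially encoded). The male dosage compensation RNAs roX1 and roX2 ranged from 869.2 to 1775 CPM and from 27.0 to 87.8 CPM over the libraries (adjusted p = 0.71 each). In camera, the lists that did not pass had adjusted p from 0.061 to 0.89 between CT0 and CT12 and from 0.08 to 0.7 between CT6 and CT18.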

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

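The tests of gene length on CT6 replicate 1, its heat-shock genes, its Pdf level and the peptide genes were written down before their results were seen; the tests of depth, mix of neuron types, and all tests of the clock genes and of the count of harmonic genes were chosen only after.

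The heat-shock genes of CT6 replicate 1 had a mean of 11.11 log2 CPM against 9.75 to 10.38 in the other 7 libraries, and its gap to the nearest of them was 0.535 of the whole range, above Dixon's critical value for 8 samples. This was 1 of 18 measures tested over the 8 libraries, and chance flags about 1 in 20 groups. Lower depth is argued against, as its total count ranked 3 of 8 from the highest, and a bias with gene length is consistent with its position in the whole profile (rank correlation over genes of 0.684). That bias does not account for the heat-shock genes, since 14 of 15 were highest in this library with the length trend removed as well as before, nor for Pdf, which the other libraries exceeded 149-fold by their median with the trend removed and 202-fold before. Stress during dissociation and a sort with few PDF neurons stay open and untested, and time of day alone would affect CT6 replicate 2 as well, whose heat-shock mean was 10.31.

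Neuropeptide genes differed between libraries of the same time by a median SD of 0.75 log2 units, and they were not alone in this: photoreceptor (2.78), hemocyte (2.63), glia (1.51) and head cycling genes (1.38) spread more, and core clock genes (0.66) and transmitter genes (0.57) also stood at percentile 100 of random lists. Gene length is argued against, because with its trend removed the peptide genes stood at percentile 99.9 of random lists. A different mix of neuron types in each sort may contribute but cannot be told apart from other sources: the smaller rank correlation within 2 pairs of monoamine genes was 0.24 (Trh with SerT), although their Pearson correlation of 0.84 rests on 2 libraries and ple with DAT had a rank correlation of 0.88. An uneven share of neuronal RNA would move the pan-neuronal genes as well. Their median SD between libraries of the same time was 0.27 log2 units, at percentile 45.5 of random lists, which argues against it. An uneven total yield of RNA was not tested, since normalization would remove most of it. The measure was changed from Pearson to rank after the values were seen, and no biological explanation was tested.

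The core clock genes ranked high for the 24-hour harmonic, with a mean −log10 p of 1.39. Whether chance assignment of libraries to times accounts for this is not settled. Of 101 assignments, 4 gave a value as large, the real one included, with 1.65 the highest of the others. This measure was chosen after the data were seen, and only 100 of 315 distinct regroupings were drawn. The clock index test of the Results, chosen before, did not pass. Gene length is argued against, because the mean rose to 1.736 with the length trend removed, against at most 1.617 in other assignments. A varying share of clock neurons between sorts, which would make Clk rise and fall with the mean of the evening genes over the 8 libraries, is neither supported nor excluded: their correlation was −0.46 (exact permutation p = 0.25) and their rank correlation −0.5 (exact p = 0.22), while with the length trend removed these were −0.75 (exact p = 0.03, adjusted over 6 relations 0.06) and −0.83 (exact p = 0.015, adjusted 0.045). Only the last of these 4 values passed after adjustment, under a correction chosen after the data were seen, so the explanation stays open; this test replaced one on the opposite changes of Clk and vri, which are among the genes to be explained. A change of clock transcripts with time of day in neurons with mor RNA interference is also consistent with these values, and the comparison with a control genotype was not analysed here.

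For the 517 genes with an unadjusted harmonic p under 0.05, chance cannot be excluded: 27 of 101 assignments gave as many, with a median of 313 in the others than the real one. The highest other gave 1785, several times the real count, which may point to a structure of the libraries. The libraries differed in how counts followed gene length, but whether that accounts for the 1785 was not tested.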

How the results depend on the processing

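Removing the gene length trend, the robust prior and every alternative for the core clock list were chosen after the data were seen. So were, for named genes, the filters, TPM and no mitochondrial genes. The adjustment over a list alone was not among the tests written down beforehand. The mitochondrially encoded list was replaced once its symbol pattern matched none. The other settings, like the main tests and the other lists, were chosen before the data were examined.

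The counts of 0 genes stayed at 0 under RLE normalization, the stricter filter, limma-voom, TPM, the replicate block, the length offset, the robust prior, no mitochondrial genes, the libraries of a contrast alone and the removal of the length trend. DESeq2 gave 28 genes changing over time, 33 with a 24-hour harmonic, 5 with a 12-hour component, 12 between CT12 and CT0 and 47 between CT18 and CT6. Without a filter edgeR gave 249, 250 (tim, vri and Clk among them), 56, 101 and 192 in that order, with infinite prior degrees of freedom against 5.4, and 4 of the 250 lay below the usual filter. Infinite prior degrees of freedom mean that each gene's own spread was not used. Beyond this the cause was not tested. Leaving out a library gave 0 to 5, 0 to 1, 0 to 2, 0 to 1 and 0 to 1, the lone library of a time being assumed to vary like the others; the 5 came without CT18 replicate 2.

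The core clock genes passing over the list alone were 4, 0 with log2 TPM plus 1 and no filter, and 1 to 4 with a library left out (1 without CT0 replicate 1, 2 without CT12 replicate 2). In the remaining settings they were 3 to 5. The exact p of the clock index ran from 0.048 (without CT6 replicate 1) to 0.23, with 0.12 in the replicate block. That of mor ran from 0.029 (without either CT6 library) to 0.3, with 0.25 in the replicate block. Marker lists stayed at 0 with log2 TPM and with the length trend removed, where again no list could pass on its own.

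The lists between CT12 and CT0 were 5, with 0 by an estimated correlation, 0 by fry, 2 with the length trend removed, 7 in the replicate block and 4 to 10 with a library left out (10 without CT0 replicate 2). Between CT18 and CT6 they were 8, with 0 by an estimated correlation, 0 by fry, 7 with the length trend removed, 8 in the replicate block and 7 to 10 with a library left out. Of the 8, 4 passed in the same direction with the length trend removed, 1 in the opposite one and 3 did not pass. Of 74 named genes, 58 kept their side of the threshold in DESeq2 and 16 newly passed; without a filter 43 of 75 kept it and 32 newly passed. In the other settings every named gene tested kept it (65 under the stricter filter, 73 without mitochondrial genes, 75 elsewhere). The libraries were not treated as paired by number, since correlations of deviations between times ran from −0.066 to 0.23, with 1 of 6 above 0.1. Something shared by number is not excluded: at each time replicate 1 had the higher total and mitochondrial share (0.111% to 0.192%, against 0.069% to 0.098%) and replicate 2 the higher cry. Depth limits genes near 3 counts per library. It does not limit mor, which had 2144 counts in all but 21.8 and 7.9 CPM in the CT6 libraries.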

Other observations

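All tests in this part were chosen after the data were seen, and its values carry no explanation.

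Other neuropeptide genes, 17 in all, had a median SD between libraries of the same time of 1.98 log2 units, above all 10000 random lists of like expression (percentile 100). Eh was at 2512 CPM in CT18 replicate 1 and at most 9.9 CPM elsewhere. Lk was at 1021 CPM in CT6 replicate 1 and at most 87.2 CPM elsewhere. Crz ranged from 527.9 to 14174 CPM and Hug from 1380 to 9962 CPM.

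The most abundant transcript was assigned to CG12239 (X 5792140 to 5794543), with 0.64% of counts in CT18 replicate 1 and 5.59% in CT0 replicate 1. The neighbouring lncRNA:CR44832 (X 5790952 to 5791536, on the opposite strand) ranged from 2403 to 12324 CPM. CG8401 ranged from 18.2 to 2663 CPM.

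Nuclear ribosomal RNA took 2.69% and 2.54% of counts at CT0, 2.76% and 2.12% at CT6, 2.09% and 1.89% at CT12, and 1.71% and 1.34% at CT18.

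Over the 8 libraries 6 relations were computed, with exact permutation p-values adjusted over the 6. The heat-shock mean and the oxidative phosphorylation mean had r = −0.89 (exact p = 0.00077, adjusted 0.0042) and rho = −0.86 (exact p = 0.011, adjusted 0.033), with r = −0.86 without the 2 farthest libraries. With each library's length trend removed this relation did not hold, with r = 0.34 (exact p = 0.45, adjusted 0.48) and rho = 0.19 (exact p = 0.66, adjusted 0.66). The dopamine genes ple and DAT had r = 0.92 (exact p = 0.0014, adjusted 0.0042) and rho = 0.88 (exact p = 0.0072, adjusted 0.033), with r = 0.87 without the 2 farthest; with the length trend removed r was 0.9 (exact p = 0.0014, adjusted 0.0084) and rho 0.93 (exact p = 0.0022, adjusted 0.013). Trh and SerT had r = 0.84 (exact p = 0.018, adjusted 0.036) but rho = 0.24 (exact p = 0.58, adjusted 0.58) and r = −0.76 without the 2 farthest, so the relation rests on those libraries. With the length trend removed r was 0.75 (exact p = 0.029, adjusted 0.06). The heat-shock mean and mor had r = 0.73 (exact p = 0.042, adjusted 0.063) and rho = 0.79 (exact p = 0.028, adjusted 0.056), with r = 0.3 without the 2 farthest and 0.63 (exact p = 0.087, adjusted 0.13) with the length trend removed. Clk and the evening genes had r = −0.46 (exact p = 0.25, adjusted 0.3) and rho = −0.5 (exact p = 0.22, adjusted 0.26), with r = −0.42 without the 2 farthest. With the length trend removed r was −0.75 (exact p = 0.03, adjusted 0.06) and rho −0.83 (exact p = 0.015, adjusted 0.045). Pdf and the clock index had r = −0.32 (exact p = 0.46, adjusted 0.46) and rho = −0.6 (exact p = 0.13, adjusted 0.2), with r = −0.84 without the 2 farthest and −0.3 (exact p = 0.48, adjusted 0.48) with the length trend removed.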
